A study of Mus musculus with 2 samples.

How the data were processed

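Total RNA was measured in 2 libraries of mouse embryonic facial prominence at embryonic day 14.5, made from 10.0 ng of RNA each after mirVana extraction with a SMART-seq protocol, per the labels. Both belong to a single group, and their biological replicate numbers come from the labels. The labels also name RNA over a size limit and added spike-in RNAs. They call each sample the face of a single embryo, with separate collection days, and elsewhere call the tissue pooled from both sexes.

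The deposited gene and transcript tables hold RSEM-style estimates for genome build mm10 with GENCODE release M4, per the companion text of each library, with each library estimated on its own. The aligner, the version of the quantifier, trimming and strand handling are not given in the sources used here. Expected counts are the authors' estimated reads per gene or transcript, not scaled to depth, per the file headers. TPM values are the authors' expected counts divided by effective length and scaled to the same total over all features, spike-ins included, as the deposited columns show. FPKM values were deposited beside them, per the file headers, and served as an alternative. Transcript percentages are the authors' percent of a gene's TPM, per the file headers. Effective length is most often 99 bases under the length, so that short RNAs reach a high TPM from few counts.

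Gene names, biotypes and positions came from GENCODE M21, on the same build, matched by Ensembl identifier without its version. Of 43346 Ensembl genes 42462 (98.0%) had a symbol. The tables also hold 96 spike-ins, 1 phiX sequence and 26248 sequences with numbers as identifiers, which entered no comparison. Depth was 30919488 expected counts for replicate 1 and 37738872 for replicate 2. Exact binomial intervals at the 95% level, on rounded expected counts, and the floor of 3 counts cover counting error only.

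A gene was called expressed at 1 TPM or more. Ratios between replicates used log2(TPM + 1), which understates the change of low genes, and genes with a mean TPM of 5 or more. For 40 gene lists with 528 different genes, of which 417 reached 1 TPM in both libraries, the number of members expressed and the levels were computed. Of the listed symbols 6 were not matched and were not used here. Lists with 5 or more members at a mean of 1 TPM were compared by the percentile of their median ratio among 10000 random lists of the same size, matched on mean TPM in 20 bins. Spike-ins with a mean count of 10 or more were set against the 20 genes nearest in count with a two-sided permutation test of 100000 resamples. Near-copies were found with BLAST 2.17.0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used, the last 2 packages for scaling factors alone, on expected counts rounded to whole numbers.

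The lists, the thresholds, the tests and the rule for named genes were fixed before the data were examined. The rule names the 10 most abundant nuclear genes, the 3 highest members of each list and the lowest in lists of 6 or more, the 10 largest ratios in each direction, all Dlx, globin and Y-linked genes with Xist and Tsix, and the isoform genes with the largest and smallest top share. Some genes that the rule names are not reported here. Genes named outside it are said to be chosen after their values were seen. Alternatives were other thresholds, pseudocounts, units, scalings, matching and filters and each replicate left out. A rule for protein-coding genes with a mean count of 100 and an effective length of 200 or more, ratios centred on the median, and lists drawn from protein-coding genes alone were added after the data were seen.

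Lists for choroid plexus, retinal pigment epithelium and fetal genes that decline with gestation were written before their values were seen. Lists for motile cilium, tendon, adipocyte and nasal and salivary gland were added before their own list values were seen but after other results, among them 6 cilium genes.

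The scripts were tested on simulated data. The 2-fold rule called 45.5%, 98.5% and 100% of 200 genes changed 2-fold, 3-fold and 4-fold among 11437 genes. It called at most 0.0623% of unchanged ones, counted in the direction of the change alone. The simulated gene noise had an SD of 0.2 on the log2 scale before counting noise, where the SD of the log2 ratio in the data was 0.28. The list percentile lay outside the central 95% for 2% of unshifted lists of 15 genes and for 100% of those shifted by 0.3 on the log2 scale, among 15609 genes. The spike-in test called 2% of simulations with equal spread and 96% of those with a spread of 0.05 against 0.2. These simulations used counts in place of TPM and no shift of the spike-ins against the genes. A difference in spread as small as that in the data was not simulated, so they do not give the power of the test for it.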

Results

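Total RNA was profiled from the facial prominence of mouse embryos of strain B6NCrl at embryonic day 14.5, when the tissue holds the forming jaws, palate, nose, teeth, skin, muscles and nerves of the face. The series has 1 group of 2 biological replicates, each labelled as the face of a single embryo and collected on a different day, so it describes a tissue and the difference between 2 libraries and compares no conditions. The library of replicate 1 held 30919488 expected counts and that of replicate 2 held 37738872. At an effective length of 2000 bases, a count of 0 allows up to 0.0761 TPM, the length-normalised transcript abundance, in replicate 1 and 0.0589 TPM in replicate 2. Intervals and floors cover counting error only, since the reads carry no molecular identifiers that were used here. With 2 samples no exact sign permutation can give a two-sided p under 0.5, so no test across embryos was made. Levels are means of TPM ± SD over both libraries, with n = 2 throughout.

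Protein-coding genes took 89.97% ± 1.71 (SD, n = 2) of the counts, and 13717 of the 21474 protein-coding genes with a symbol reached 1 TPM in both embryos. Over all classes 15127 genes did so, 187 of them long intergenic non-coding RNAs. Mitochondrial genes took 1.75% ± 0.108 of the counts, globins 1.05% ± 0.126 and replication-dependent histones 0.0893% ± 0.00373. The mitochondrial share may be too low. It leaves out Gm28437, a nuclear pseudogene identical to mitochondrial mt-Co3, with 123784 counts in replicate 1 and 158584 in replicate 2. The synthetic spike-in RNAs, added by the laboratory to each sample, took 3.22% in replicate 1 and 5.43% in replicate 2. Shares of TPM were larger for short RNAs, at 3.33% for mitochondrial genes, 9.45% for spike-ins and 3.16% for globins.

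The most abundant nuclear genes were blood, structural RNA and housekeeping genes. Gm42418, a non-coding gene that overlaps a ribosomal RNA repeat (chromosome 17, 39846958 to 39848788, mm10), stood first at 15129 ± 88.7 TPM. The globin genes Hba-a2, in second place, Hbb-bs, Hbb-bt and Hba-a1 had 13539 ± 1195, 6997 ± 1307, 5196 ± 376 and 5053 ± 401 TPM. Rn7s2 and Rn7s1, genes of the 7SL RNA of the signal recognition particle, reached 8934 ± 1687 and 8933 ± 1686 TPM. Actb, the cytoskeletal beta-actin, had 4994 ± 673 TPM, and Eef1a1, a translation elongation factor, had 4826 ± 395 TPM. Gm28437, a nuclear pseudogene on chromosome 1 at 9138 ± 56.4 TPM, is 100% identical to mitochondrial mt-Co3 over its 783 bases, so its level cannot be separated from that gene. The same holds for Rn7s1 and Rn7s2, which are identical over 300 bases, and in part for Hba-a1 and Hba-a2, which share 99.8% of 538 aligned bases.

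The regulators of facial mesenchyme were all expressed. All 39 listed regulators of cranial neural crest and facial mesenchyme reached 1 TPM in both embryos, with a median of 11.6 TPM. Prrx1, a homeobox gene of limb and facial mesenchyme, was the highest at 79.5 ± 0.976 TPM, followed by Osr2, which acts in palate growth, at 69.8 ± 14.5 TPM. Msx1, required for tooth and palate formation (chromosome 5, 37820485 to 37824583), had 61.4 ± 8.08 TPM. Hand1 was the lowest at 1.28 ± 0.0849 TPM. Between the embryos the list differed by no more than matched random lists, at percentile 19.3 of 10000.

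All 6 Dlx genes, which pattern the pharyngeal arches from upper to lower jaw, were expressed, with a summed level of 66.0 TPM in replicate 1 and 64.4 TPM in replicate 2. Dlx5 (chromosome 6, 6877805 to 6882085) had 30.6 ± 0.148 TPM, Dlx3 14.21 ± 1.63, Dlx1 11 ± 1.65, Dlx2 4.37 ± 0.297, Dlx6 2.54 ± 0.629 and Dlx4 2.46 ± 0.0495 TPM. The list lay at percentile 70.2 between the embryos. Hox genes, which pattern the body from the hindbrain backwards, were lower, with a smaller share of them expressed. Of the 12 Hox genes of paralogue groups 1 to 4, 7 reached 1 TPM in both embryos, led by Hoxa2, the selector gene of the second arch, at 7.5 ± 2.54 TPM, Hoxb2 at 6.44 ± 1.10 TPM and Hoxd1 at 3.35 ± 0.587 TPM. Hoxb1 had 0.1 TPM in each library, from 2 and 4 counts.

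Of the 27 Hox genes of groups 5 to 13, 4 reached 1 TPM in both embryos, with 8 in replicate 1 and 4 in replicate 2, so leaving out replicate 2 raised the count to 8. Hoxd8 was the highest at 7.46 ± 1.18 TPM, before Hoxa5 at 2.23 ± 0.594 and Hoxd9 at 1.73 ± 0.233 TPM, and Hoxd12 had 0 counts in both. Chosen after their values were seen, Hoxa7, Hoxa9 and Hoxa10 had 41.8, 60 and 48 counts in replicate 1 against 4.72, 4 and 0 in replicate 2. The ratio of replicate 2 to replicate 1 in CPM was 0.0546 for Hoxa9, with an exact 95% counting interval of 0.0144 to 0.147. The summed level of these 27 genes was 25.7 TPM in replicate 1 and 14.3 TPM in replicate 2. Between the embryos groups 1 to 4 lay at percentile 2.86 and groups 5 to 13 at 2.5, the edge of the central 95% of random lists, and both lay below it under both count scalings and among protein-coding genes alone.

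Cartilage genes were expressed in both embryos and most were lower in replicate 2. All 20 chondrocyte genes reached 1 TPM in both, led by the cartilage collagens Col2a1 at 384 ± 141 TPM (chromosome 15, 97975602 to 98004695), Col9a3 at 181 ± 72.7 and Col11a1 at 134 ± 4.91 TPM. Ucma, a matrix protein of the growth zone, was the lowest at 2.06 ± 0.368 TPM. The median log2 ratio of replicate 2 to replicate 1 was −0.63, which is −0.49 relative to matched random lists and lies at percentile 0 of 10000 of them, with 4 of 20 genes above the median of all genes. Chosen after their values were seen, Matn1, a cartilage matrix protein, had 104 TPM in replicate 1 and 39.3 TPM in replicate 2, and the 4 were Col11a1, Sox6 at 9.86 and 9.55 TPM, and Col10a1 and Ucma, which were higher in replicate 2 with 3.4 and 4.91 TPM and 1.8 and 2.32 TPM.

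Bone genes were abundant and went the other way. All 15 early osteoblast genes were expressed, with Col1a1 and Col1a2, the chains of type I collagen, at 3276 ± 454 and 2204 ± 219 TPM, and Sparc, a bone matrix protein, at 2354 ± 209 TPM. Phex was the lowest at 5.49 ± 0.460 TPM. Their median log2 ratio was 0.20, or 0.33 above matched random lists, at percentile 100, and all 15 lay above the median of all genes. The osteoclast list, of bone-resorbing cells, had 6 of 9 members at 1 TPM in both, among them the proteases Ctsk at 103 ± 14.5 TPM and Mmp9 at 34.1 ± 8.92 TPM and the phosphatase Acp5 at 22.1 ± 7.47 TPM, while Oscar had 0.275 ± 0.134 TPM. Its median ratio was 0.48, at percentile 99.99.

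Of the 6 genes of osteocytes and mature bone, 3 reached 1 TPM in both. Dmp1, of osteocytes, had 15.9 ± 1.68 TPM, and Fgf23 had 0 counts in both. The osteocalcin genes Bglap (chromosome 3, 88383501 to 88384464) and Bglap2 had 15.8 ± 13.3 and 12.8 ± 10.7 TPM. Both were higher in replicate 2, with a ratio of CPM of 4.14 (exact 95% counting interval 2.95 to 5.93) for Bglap. The split between these genes is uncertain because they share 98.9% of 439 aligned bases.

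Early tooth genes were expressed and mature tooth matrix was nearly undetected. Of 12 early tooth genes 9 reached 1 TPM in both, with Sostdc1, a modulator of Bmp and Wnt signalling, at 66.4 ± 3.33 TPM and Lef1 at 23.7 ± 4.72 TPM. Shh, expressed in the enamel knot, was at 0.435 ± 0.0778 TPM. The list lay at percentile 60.7 of matched lists. Of 8 enamel and dentine matrix genes, Ambn (ameloblastin) alone reached 1 TPM in both, at 5.67 ± 1.62 TPM. Odam had 0.850 ± 0.665 TPM, Amtn 0.190 ± 0.269 TPM, and Dspp 0 counts in both.

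Skeletal muscle was well represented. All 26 listed muscle genes were expressed, with a median of 250.3 TPM, led by the actins Acta1 at 2096 ± 498 and Actc1 at 1831 ± 139.9 TPM and the myosin light chain Myl1 at 1140 ± 266 TPM. Pax7, of muscle progenitors, was the lowest at 2.02 ± 0.127 TPM. The list was higher in replicate 2 by a median log2 ratio of 0.18, or 0.30 above matched random lists, at percentile 100, with 25 of 26 genes above the median of all genes. Of the 4 myosin heavy chains of adult muscle, 2 reached 1 TPM in both, Myh7 at 46.8 ± 1.43 and Myh1 at 2.00 ± 0.318 TPM, and Myh2 had 0.825 ± 0.361 TPM.

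The surface epithelium was present with genes of its basal and outer layers. All 16 basal epithelial genes were expressed, led by the keratins Krt14 at 299 ± 1.56 and Krt15 at 153 ± 37.6 TPM and by the desmosome gene Perp at 201 ± 22.02 TPM, with Grhl2 lowest at 6.36 ± 0.219 TPM. The list did not differ between embryos beyond matched lists, at percentile 38.0. Of 14 genes of the periderm and cornified layers 12 reached 1 TPM in both, with Krtdap at 382 ± 53.9, Krt17 at 109.8 ± 7.73 and Sfn at 104 ± 7.57 TPM, and Flg (filaggrin) at 0.005 ± 0.00707 TPM. This list had the largest median ratio of the 30 compared, at 0.71, or 0.86 above matched random lists, at percentile 100, with 9 of 12 genes above the median of genes at 1 TPM. The suprabasal keratin Krt13 had 7.73 TPM in replicate 1 and 46.1 TPM in replicate 2, and Lor (loricrin, of the cornified envelope) 2.45 and 16.2 TPM. Chosen after their values were seen, Krt6a had 28.5 and 92.1 TPM and Cnfn 14.21 and 60.7 TPM. Among those not above it, also chosen afterwards, were Grhl3, a regulator of periderm, with 17.2 TPM in replicate 1 and 10.2 TPM in replicate 2, and Sfn with 109.1 and 98.39 TPM.

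Neural and pigment cell genes of the face were detected at moderate levels. All 14 sensory ganglion genes were expressed, with Tubb3, a neuronal tubulin, at 71.4 ± 12.9, Stmn2 at 63.3 ± 1.90 and the neurofilament gene Nefl at 55.3 ± 5.47 TPM. All 10 glial genes were expressed, with Fabp7 at 69.5 TPM in each library, Erbb3 at 17.8 ± 0.636, Sox10 at 12.96 ± 0.226 and Foxd3 at 1.33 ± 0.304 TPM. Of 17 olfactory and vomeronasal genes 13 reached 1 TPM in both, among them the G protein gene Gnai2 at 311 ± 32.7, the growth cone gene Gap43 at 114 ± 9.62 and Cbr2 at 67.7 ± 28.2 TPM, and Trpc2 was at 0.125 ± 0.177 TPM. Of 7 melanocyte genes 4 did, with Pmel at 10.8 ± 0.368, Dct at 6.70 ± 0.721 and Mlana at 2.44 ± 0.382 TPM and Slc45a2 at 0.450 ± 0.127 TPM. None of these 4 lists lay outside the central 95% of random lists, with percentiles of 15.97 for sensory ganglion, 43.9 for glia, 67.6 for olfactory and 86.4 for melanocyte genes.

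Vessels and immune cells were expressed throughout their lists. All 14 endothelial genes reached 1 TPM in both embryos, with Plvap at 43.5 ± 1.07, Esam at 41.6 ± 2.98 and Pecam1 at 37.5 ± 2.74 TPM and the lymphatic regulator Prox1 at 3.35 ± 0.304 TPM. The list was at percentile 90.3, and above the central 95% of random lists under both count scalings and among members at 5 TPM. All 10 pericyte and smooth muscle genes were expressed, with Acta2 at 344 ± 5.14, Pdgfrb at 36.8 ± 3.30, Tagln at 35.0 ± 1.92 and Myh11 at 2.58 ± 0.580 TPM. Their percentile was 99.4, and 95.4, inside the central range, among members at 5 TPM. All 13 macrophage and leukocyte genes were expressed, with the lysozyme gene Lyz2 at 102 ± 19.3, Pf4 at 85.6 ± 13.98, Fcer1g at 75.6 ± 0.813 and Ptprc at 2.88 ± 0.148 TPM. That list was higher in replicate 2 relative to matched lists by 0.17, at percentile 99.8.

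The embryos differed in their embryonic globins. Hbb-y (chromosome 7, 103851749 to 103853216) had 717 ± 615 TPM, from 1152 TPM in replicate 1 and 283 TPM in replicate 2, Hba-x 170.0 and 62.2 TPM, and Hbb-bh1 6.50 and 2.74 TPM. Relative to the median gene the log2 ratios of these 3 genes were −1.88, −1.29 and −0.86. The 4 adult-type globins Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 had ratios of 0.53, 0.30, 0.31 and 0.33 relative to the median gene. The embryonic genes made up 4.46% of globin TPM in replicate 1 and 1.04% in replicate 2. Of 9 other erythroid genes 6 reached 1 TPM in both, with the haem synthesis gene Alas2 at 71.2 ± 5.35 and the transferrin receptor Tfrc at 31.7 ± 1.37 TPM and Rhag at 0.330 ± 0.0707 TPM. That list lay at percentile 89.0. The split between Hbb-bs and Hbb-bt is uncertain, as they share 94.9% of 585 aligned bases.

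Markers of neighbouring and distant organs were low with named exceptions. Of 14 brain genes 2 reached 1 TPM in both, Emx2 at 5.71 ± 0.594 and Otx1 at 2.19 ± 0.0919 TPM, with Olig2 at 0.975 ± 0.120 and Neurod6 at 0.0350 ± 0.0212 TPM. Of 10 pituitary genes 4 did, Pitx1, which the lower jaw also uses, at 33.1 ± 4.33, Pomc at 18.8 ± 2.90 and Cga at 4.58 ± 0.0212 TPM among them, and Gh had 0 counts in both. Of 14 lens and retina genes 5 did, with Cryab, which muscle also expresses, at 134 ± 17.7, Bfsp2 at 2.75 ± 0.0778, Bfsp1 at 2.65 ± 0.361 and Cryba1 at 0.0350 ± 0.0495 TPM. Of 8 heart genes 4 did, with Myl2 at 36.7 ± 8.83, Nkx2-5 at 6.02 ± 0.537, Tnni3 at 2.83 ± 0.813 and Nppa at 0.0550 ± 0.0778 TPM. Of 9 liver genes Apoa2 alone did, at 1.48 ± 0.0990 TPM, with Alb at 1.04 ± 0.106 and Fgb at 0.05 ± 0.0283 TPM. Ttr (transthyretin, a carrier of thyroid hormone and retinol) had 0.450 TPM in replicate 1 and 60.2 TPM in replicate 2. The pituitary list lay at percentile 51.4 and the lens and retina list at 97.1, and past the central 95% of random lists under both count scalings.

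**Figure D1:**
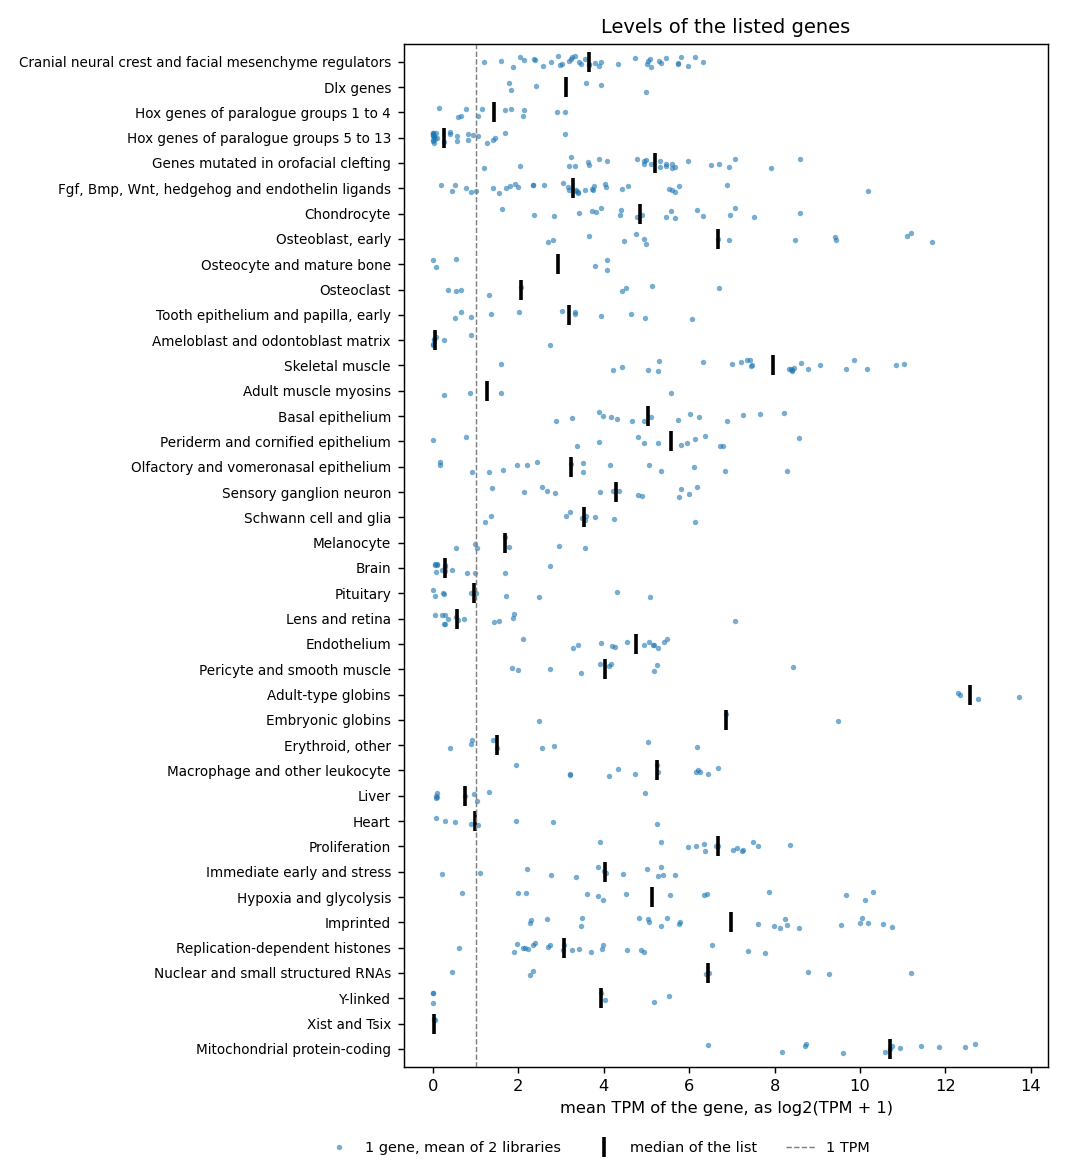
Mean TPM of each listed gene over the 2 libraries, on the log2(TPM + 1) scale, by gene list, with the median of each list as a black bar and 1 TPM as a dashed line. Adult-type globins, mitochondrial protein-coding and skeletal muscle genes have the highest medians, and enamel and dentine, brain and posterior Hox genes lie mostly under 1 TPM.

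Signalling ligands of the face were led by growth factors of the insulin family. Of 36 listed ligands 30 reached 1 TPM in both, with Igf2 at 1157 ± 29.7, Igf1 at 116 ± 13.4 and Pdgfa at 53.5 ± 6.53 TPM, and Fgf8, an early signal of the facial ectoderm, at 0.140 ± 0.0849 TPM. The list lay at percentile 3.39 and below the central 95% of random lists under both count scalings and among protein-coding genes alone. All 28 genes mutated in orofacial clefting were expressed, led by Col2a1, the actin-binding Flna at 241 ± 33.1 TPM and Col11a1, with Foxe1 lowest at 1.28 ± 0.0354 TPM. Their median log2 ratio was −0.09 relative to matched lists, at percentile 0.3. Without the genes that stand in another list, such as the cartilage collagens, the percentile was 26.1, and under both count scalings it was 2.72.

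Proliferation genes were expressed throughout and lower in replicate 2. All 15 reached 1 TPM in both, with the cell cycle kinase Cdk1 at 325 ± 35.7, Birc5 at 194 ± 28.6 and Pcna at 180.3 ± 16.7 TPM and Bub1 at 14.02 ± 1.81 TPM. Their median log2 ratio was −0.28, or −0.14 relative to matched lists, at percentile 0.08. Of 23 replication-dependent histone genes 22 reached 1 TPM in both, with Hist1h4d at 218 ± 29.1, Hist1h2ae at 166 ± 15.9, Hist1h2bc at 91.3 ± 19.6 and Hist1h4a at 0.520 TPM. The histone list lay at percentile 2.29, and inside the central range, at 2.86 to 3.86, under both count scalings and among members at 5 TPM. Of the 22 histone genes compared, 9 lay above the median of genes at 1 TPM. The class of all 67 such histone genes took 0.0867% of the counts in replicate 1 and 0.0920% in replicate 2.

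All 24 imprinted genes were expressed, with a median of 124 TPM. Mest had 1729 ± 195 TPM, the growth inhibitor Cdkn1c 1490 ± 78.6 and Igf2 1157 ± 29.7 TPM, and Kcnq1ot1 3.85 ± 0.361 TPM. Of 14 hypoxia and glycolysis genes 13 were expressed, with the glycolytic genes Ldha at 1271 ± 124, Eno1 at 1106 ± 140.3 and Aldoa at 810.3 ± 24.1 TPM and Car9 at 0.615 ± 0.403 TPM. Neither list stood apart between embryos, at percentiles 17.6 and 25.6. Of 14 immediate early and stress genes 12 were expressed, with the chaperone genes Dnajb1 at 49.4 ± 2.34 and Hsph1 at 40.8 ± 3.63 TPM, Jun at 39.5 ± 1.85 TPM and Fosb at 0.160 ± 0.0707 TPM. That list was higher in replicate 2 by 0.16 relative to matched lists, at percentile 99.7.

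Among nuclear and small structured RNAs 7 of 8 were expressed, with Malat1 at 2353 ± 3.14, Gas5 at 616 ± 11.3 and Rn7sk at 440.3 ± 43.2 TPM and the telomerase RNA Terc at 0.355 ± 0.163 TPM. The list lay at percentile 93.1, and at 99.4 without the gene that stands in another list. All 13 mitochondrial protein-coding genes were expressed, with mt-Atp6 at 6587 ± 256, mt-Atp8 at 5648 ± 109.7 and mt-Cytb at 3685 ± 0.714 TPM. The lowest, mt-Nd4l, had 140.2 TPM in replicate 1 and 31.6 TPM in replicate 2. The mitochondrial list lay at percentile 97.6, and at 95.9 among members at 5 TPM.

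The most abundant transcript was the same in both embryos for most genes. Among 8135 genes with at least 5 TPM in both embryos and 2 or more transcripts, 7559 (92.9%) had the same most abundant transcript in both, with a median share of 71.4% for it. Among genes of the isoform list with several transcripts and 5 TPM or more in both embryos, the top transcript of Col1a1 took the largest share, at 99.4% ± 0.134, and that of the bone regulator Runx2 the smallest, at 31.0% ± 1.25. Twist1 and Sox9 have a single annotated transcript. The list's most abundant genes were Col1a1, Myl1 and the imprinted RNA Meg3, at 1060 ± 136 TPM, and its lowest was the vessel growth factor Vegfa at 3.50 ± 0.120 TPM. Chosen after their values were seen, the Col2a1 transcript ENSMUST00000088355.7, without the alternative exon, took 69.8% ± 0.615 of Col2a1, and ENSMUST00000023123.10, which holds exon 2 (chromosome 15, 98000403 to 98000606, 204 bases), took 28.1% ± 0.530. The pyruvate kinase transcript ENSMUST00000034834.11 took 83.9% ± 4.11 of Pkm.

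Y-linked genes were expressed in both libraries and Xist, the RNA that coats the inactive X chromosome of females, was close to undetected. The question arises because the labels call the tissue both a single embryo and pooled from both sexes. Ddx3y had 36.7 TPM in replicate 1 and 33.6 TPM in replicate 2, Eif2s3y 50.8 and 38.8 TPM, Kdm5d 16.9 and 13.9 TPM and Uty 14.8 and 14 TPM. Zfy1, Zfy2 and Usp9y had 0 counts in both libraries, which allows up to 0.0558, 0.0557 and 0.0190 TPM in replicate 1. Xist (chromosome X, 103460366 to 103483254) had 3.66 counts in replicate 1 and 4.36 in replicate 2, or 0.01 TPM in each, and its overlapping antisense gene Tsix had 0.02 and 0.05 TPM. Whether the counting separated the strands is not given in the sources used here, so reads of Xist and Tsix cannot be told apart.

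The embryos were close across genes. Over 16275 genes at 1 TPM in either library, Pearson's r of log2(TPM + 1) was 0.983 and Spearman's rho 0.985. These are correlations across genes, which are not independent replicates. Among 11482 genes with a mean TPM of 5 or more the median log2 ratio of replicate 2 to replicate 1 was −0.15, with an SD of 0.28, while the median spike-in ratio was 0.63. Directions of lists are therefore given relative to other genes, and a scaling to equal spike-in sums moved the median of all genes to −0.81. Of 13459 genes with a mean count of 100 or more, 46.4% lay outside the exact 95% counting interval around the common ratio.

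The spike-ins, which cannot differ between embryos, were set against genes of similar count, and their spread did not pass a threshold of 0.05 in the test fixed beforehand. The mean absolute deviation of the log2 ratio was 0.16 for 68 spike-ins and 0.21 for the matched genes, a difference of −0.05 (two-sided permutation test over spike-ins and genes, 100000 resamples, p = 0.0813). At a minimum mean count of 50 the permutation p was 0.00957, on expected counts 0.0111, and with 5 matched genes 0.311.

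**Figure D2:**
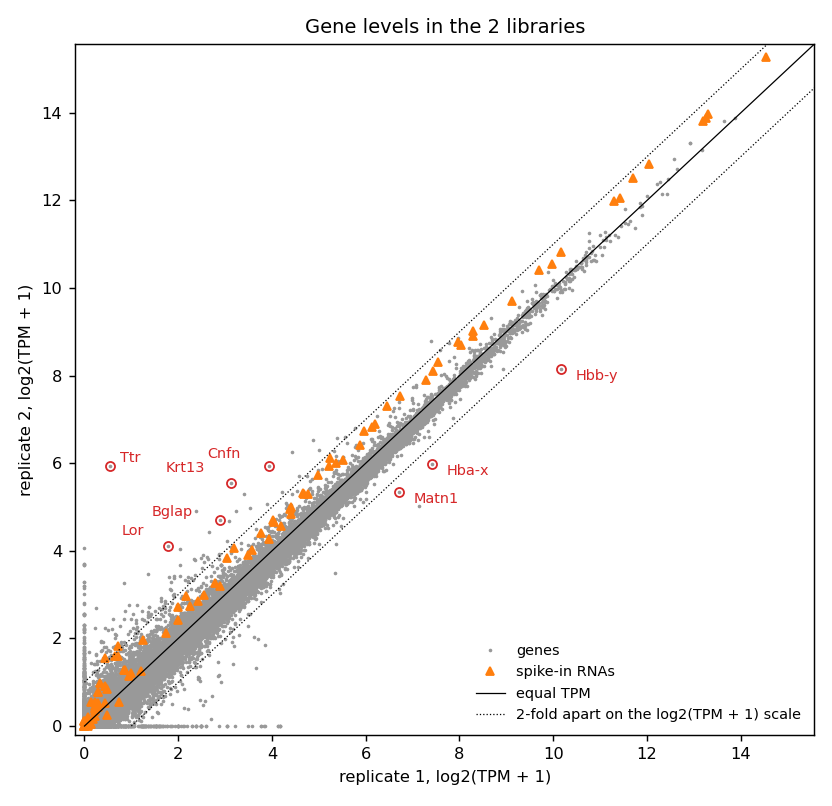
TPM of each gene in replicate 1 (horizontal) and replicate 2 (vertical), both on the log2(TPM + 1) scale, with genes as grey points, spike-ins as orange triangles, equal TPM as a solid line and 2-fold differences as dotted lines. Red circles mark 8 genes chosen after their values were seen, and most genes lie close to the diagonal, with Pearson's r of 0.983 over 16275 genes.

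Few genes differed by 2-fold or more. Of the 11482 genes, 54 were at least 2-fold higher in replicate 2 and 28 in replicate 1, together 0.714%, on TPM as given. The split depended on the processing, with 69 and 25 after centring on the median of all genes, an alternative added after the data were seen, 54 and 12 on counts without length normalisation under TMM and under DESeq2 size factors, 19 and 1269 at equal spike-in sums, and 39 and 5 among 10860 protein-coding genes with longer transcripts and more counts, a rule added after the data were seen. Of the 20 genes named by their size of change, 13 had an effective length under 200 bases, 15 had 0 counts in 1 library and 5 were protein-coding. Ttr (chromosome 18, 20665280 to 20674321) led those higher in replicate 2 with 10 and 1718 counts, a ratio of CPM of 141 (exact 95% counting interval 76.4 to 294). Krt13 followed among protein-coding genes with a ratio of 6.25 (5.45 to 7.18), then Lor with 7.01 (5.56 to 8.94) and Lrrc23, a gene of motile cilia, with 5.40 (3.90 to 7.67), and the pseudogene Gm10171 had 7.24 (5.29 to 10.1).

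The other genes of this rule higher in replicate 2 were the small RNA genes Gm27624, Gm26244, Gm24924, Rnu3b3 and Rnu3b1, with 0 counts in replicate 1 and 19.8 to 35 in replicate 2. On the side of replicate 1, Gm10273 had 272 counts against 0, Rpl30-ps9 had 52.9 against 0, and Rnu3b4 and Rnu3b2 had 38 each against 0. Copies of the U3 RNA gene, Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4, are identical over 216 bases and took opposite sides, so their split is uncertain. Gm27883, Gm26049, Rny3, Mir719, Gm23167 and Gm22392 had 1 to 3 counts in replicate 1 and 0 in replicate 2, with counting intervals of the ratio that reach past 1.

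Of the 40 lists, 30 could be compared between embryos. By percentile, 12 lay outside the central 95% of random lists, where 1.5 would if listed genes varied independently. Such independence was not tested for genes of 1 tissue and fails for genes that lists share. The Hox list of groups 5 to 13, at percentile 2.5, was counted as inside. Its median log2 ratio of −0.3484 lay just below the lower end of its random range, −0.3482. Lower in replicate 2 relative to matched lists, by list median, were the chondrocyte, proliferation, orofacial clefting and histone genes. Higher were the periderm and cornified, osteoclast, early osteoblast, skeletal muscle, pericyte, macrophage, immediate early and mitochondrial genes. The whole histone class took no smaller share of the counts in replicate 2. Of the 12, 8 were called in each of the settings run, and the clefting, pericyte, histone and mitochondrial lists lost the call in at least 1. Another 6 lists, of both Hox groups, ligands, lens and retina, endothelium and nuclear RNAs, were called in at least 1 other setting.

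**Figure D3:**
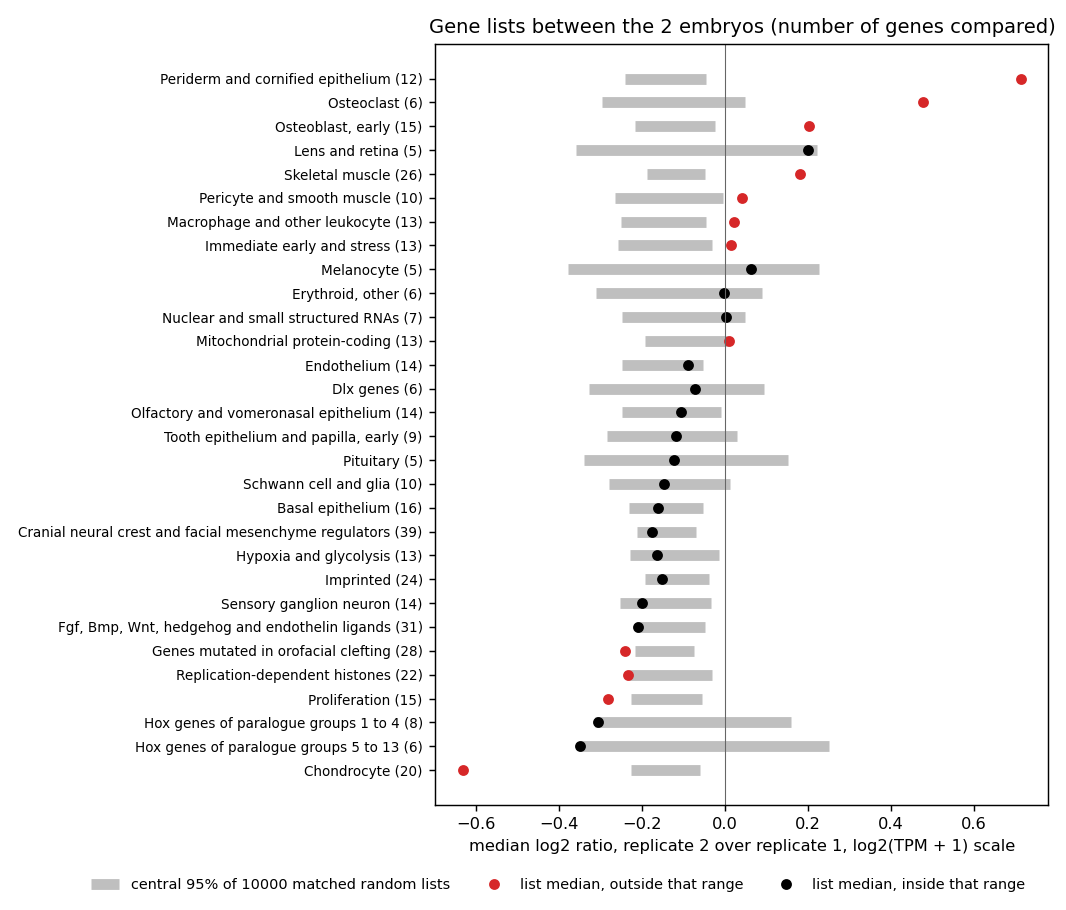
Median log2 ratio of replicate 2 to replicate 1 on the log2(TPM + 1) scale for the 30 lists compared, as points, with grey bars for the central 95% of 10000 matched random lists. Red points lie outside that range, from −0.63 for chondrocyte genes to 0.71 for periderm and cornified epithelium genes. The point for Hox genes of groups 5 to 13 lies just past the lower end of its bar. That list, at percentile 2.5, is not counted among the 12 lists outside the range by percentile.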

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

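No test in this part was chosen after its result was seen, and no explanation was weighed. Signal appeared in sequences that entered no comparison, where a count of 0 allows up to 3 counts, and what they are is not given in the sources used here. The 26248 sequences with numbers as identifiers held 14.79 expected counts in replicate 1 and 9 in replicate 2. In 6 of these sequences a count stood above 0 in either library, with at most 8 in replicate 1 and 6 in replicate 2.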

How the results depend on the processing

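The protein-coding rule, centring on the median and lists from protein-coding genes alone were tests chosen after the results were seen. None of the 12 lists outside the random range in the main setting and none of 35 named gene ratios reversed direction in the settings run for them, while the differences of the pituitary, basal epithelium, olfactory, glial and hypoxia lists, inside that range, changed sign in at least 1. Genes detected (11167 to 18550), list members expressed (333 to 434) and lists outside the random range (9 to 15) stayed within 1.5 times of their main counts in each setting run.

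Pearson's r was 0.954 with a pseudocount of 0.1, 0.994 without a filter, 0.986 on FPKM, 0.992 with TMM and 0.982 at 5 TPM. Genes 2-fold apart numbered 285 at a mean TPM of 1 (176 higher in replicate 2, 109 in replicate 1), since more low genes enter, and 21 at 20 TPM (15 and 6), as fewer do. They numbered 1288 at equal spike-in sums (19 and 1269), which shifts the median of all genes and turns the split the other way, and 44 by the protein-coding rule (5 higher in replicate 1). TMM and DESeq2, on counts without length normalisation, each gave 12 higher in replicate 1, where centring TPM alone gave 25.

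The spike-in difference was −0.0799 at a mean count of 50 (permutation p = 0.00957) and −0.114 on expected counts (permutation p = 0.0111), against permutation p = 0.311 with 5 matched genes. The log2(TPM + 1) scale pulls spike-ins of low TPM toward no change, away from the spike-in median of 0.63. The spike-in ERCC-00104, with 6 and 15 counts, had a ratio of 0.175 on it. At a mean count of 50 the mean absolute deviation was 0.108 for spike-ins and 0.187 for genes, against 0.160 and 0.206 in the main setting. How far the scale raised the main p was not tested. The same top transcript was found in 94.8% of genes at 20 TPM, 99.7% with a lead of 20 percentage points and 94.5% on expected counts. Shares of TPM in place of counts, which weight short RNAs more, were 3.33% for mitochondrial genes, 9.45% for spike-ins, 3.16% for globins, 0.328% for histones, 79.4% for protein-coding genes and 2.46% for lincRNAs. The lincRNA share includes Gm42418, which overlaps a ribosomal RNA repeat and alone took 1.51% of TPM. Leaving out a replicate gave 4 to 8 Hox genes of groups 5 to 13. Xist as a percent of Xist plus Y-linked levels was 0.00917 in TPM, 0.0566 in counts, which keep its length, and 0.0139 in FPKM, near the rounding of the deposited values. Depth limits genes near the floor of 3 counts, and 2 libraries allow no test across embryos.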

Other observations

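The tests of Xist, of Tsix, of male tissue, of blood and of liver or yolk sac cells were chosen after the result was seen, and the 4 added tissue lists after other results were, and single genes named here from the added and mitochondrial lists after their values were. Genes of motile cilia were higher in replicate 2 as a group. Of 23 genes measured 16 reached 1 TPM in both libraries, and 17 of 18 compared lay above the median of all genes, with a median log2 ratio of 0.78 at percentile 100 of matched random lists. The cilium regulator Foxj1 had 5.75 TPM in replicate 1 and 10.4 TPM in replicate 2, the radial spoke gene Rsph9 10.2 and 16.6 TPM, and Tekt1 5.04 and 9.52 TPM. Cfap43 went the other way, with 10.4 and 8.40 TPM.

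Adipocyte genes lay at percentile 99.99 with a median log2 ratio of 0.31, and 6 of 11 reached 1 TPM in both. Fabp4, a fatty acid carrier, had 46.3 TPM in replicate 1 and 95.2 TPM in replicate 2, and the fat cell hormone Adipoq 4.76 and 13.98 TPM. Nasal and salivary gland genes lay at percentile 99.9 with 5 of 12 genes compared, of which the glial list also holds Sox10, and the airway secretory gene Bpifa1 had 74.7 and 134 TPM. All 11 tendon genes were expressed, with Dcn at 539 ± 10.6 TPM (SD, n = 2) and Tnmd at 78.8 ± 10.1 TPM, and the list lay at percentile 98.2. Its median log2 ratio was −0.014, against −0.14 for matched random lists, with 7 of 11 genes above the median of all genes. Tnmd, Thbs4, Scx and Egr2 lay below that median. The mitochondrial genes mt-Nd3 and mt-Nd4l went opposite ways, with 192 and 384 TPM for the first and 140.2 and 31.6 TPM for the second.

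Y-linked genes were expressed in both libraries without Xist, while a label calls the tissue pooled from both sexes. The higher Xist level of the libraries was 0.01 TPM, which argues against a pool of male and female tissue. Xist and Tsix together reached at most 0.06 TPM, so reads given to the antisense gene do not account for the missing Xist. Of the explanations weighed, the values do not argue against male tissue alone in each library, for which 4 Y-linked genes at 1 TPM or more were counted in both. Male tissue may account for the pattern, but its prediction was written after the values were seen. No female library was used here to set the level.

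Cartilage and proliferation genes were lower, and bone, muscle and cornified epithelium genes higher, in replicate 2 relative to matched lists. Removing the trend on transcript length and GC content left 100% of the 12 lists outside the random range. That trend took 2.35% of the variance of the log2 ratio, so little was removed. The histone list moved from percentile 2.29 to 0. A different amount of blood would move lists of other tissues alike. The chondrocyte list lay below its random range, and the bone, muscle, pericyte and cornified epithelium lists above theirs, which argues against blood alone for these lists. The gap between the 2 sides was 0.839 on the log2 scale (95% interval over resampled genes 0.629 to 1.00). The sides were formed from lists already seen to differ, so the gap and its interval restate that difference and add no support. For the other lists a different amount of blood stays open, with other erythroid genes at percentile 89.05 and adult-type globins higher in replicate 2. A candidate explanation is a later developmental stage of the replicate 2 embryo, for which the list of fetal genes that decline with gestation was tested. Its 4 compared members, Igf2bp2, Igf2bp3, Igf2bp1 and Hmga2, lay at percentile 0 of matched lists and all below the median of genes. They are fewer than the 5 asked of other lists. The test cannot separate a later stage from a different make-up of the tissue taken, since the chondrocyte and proliferation lists were lower too. The summed level of the 27 Hox genes of groups 5 to 13 also differed, at 25.7 TPM in replicate 1 and 14.3 TPM in replicate 2. Within the globins, the embryonic genes took 4.46% of globin TPM in replicate 1 and 1.04% in replicate 2. No prediction was written for this share, so it was not used as a test of stage. The labels give both embryos the same age, and which part of the face was taken was not tested.

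Ttr had 10 counts in replicate 1 and 1718 in replicate 2. The summed level of Alb, Afp, Apoa1 and Apoa2 was 4.60 and 3.72 TPM, a ratio of 0.809 (exact 95% counting interval on CPM 0.632 to 1.08), beside a ratio of CPM of 141 for Ttr, which argues against liver or yolk sac cells. Rpe65, Rgr and Rlbp1, of retinal pigment epithelium, had a ratio of 0.643 (0.494 to 0.836). The list of that tissue, with 6 genes, 3 of them expressed in both libraries, lay at percentile 5.77. These values show no rise of such cells in replicate 2 but cannot exclude them. Rlbp1 held 110 and 94 of the 135 and 106 counts, Rpe65 had 0 and 1, and Lrat of the list went the other way with 14 and 37. Choroid plexus cells may be a source and stay open, since their list lay at percentile 93.96 with 62.5% of 8 genes higher in replicate 2 in TPM and 7 of 8 above the median of all genes. Of its 12 genes 8 were expressed in both libraries, with Enpp2 at 39.5 and Calml4 at 13.3 TPM as the most abundant, and Kcne2 had 3 and 70 counts.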
